A study of Homo sapiens with 16 samples.

How the data were processed

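Gene expression was measured on Affymetrix U133 Plus 2.0 arrays, which read mRNA with 54675 probe sets, in human peripheral blood mononuclear cells (PBMCs) and in 293T cells, a human embryonic kidney line. Per the labels, PBMCs of healthy donors were isolated on a density gradient and kept in medium with 10% serum, and 2.2 ug of total RNA was used. The 12 PBMC arrays comprised 3 controls, 3 from cells given 10 nM gold nanoparticles carrying an antisense EGFP oligonucleotide (AuNP) for 24 h, 3 given AuNP for 48 h, and 1 each for Oligofectamine alone (a lipid transfection reagent), Oligofectamine with the EGFP oligonucleotide, and HIV. The 4 arrays of 293T cells were a control and AuNP at 6 h, 24 h and 48 h. The labels give no time for the control, Oligofectamine and HIV arrays, and do not say whether the 3 arrays of a group came from separate cultures or donors, so the p-values measure only the spread between arrays.

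The values used throughout were the deposited log2 expression values. Each was checked to be the log2 of the deposited linear intensity matrix of all 16 arrays, which the authors made with FARMS, a factor-analysis summary of the probes of a probe set. RMA is also named by the authors, with no version and no stated part. A second deposited matrix holds FARMS intensity values that the authors summarised on the 12 PBMC arrays alone and on the 4 arrays of 293T cells alone. Per the file headers, a further column holds an informative/non-informative call as a p-value, and probe sets under 0.6 are informative. The authors also deposited the results of a SAM test, whose other columns hold an average level and a log2 difference, the SAM score, a p-value and an adjusted p. Its log2 difference matched AuNP arrays against all 6 other PBMC arrays to within 1.23e-08, not against the 3 controls, where the largest gap was 2.84.

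Of the 54675 probe sets, 30045 were non-informative over the 16 arrays, and 30029 of these held 1 value on all arrays to within 0.001. They were left out together with 62 control probe sets, which left 24572 probe sets tested. This differs from the plan, which had assumed RMA values for all probe sets. As an alternative, p-values were adjusted over all probe sets but the control ones, with those left out counted as unchanged and not tested. The planned filter on detection calls could not be run, since the values used hold no such calls. Gene names came from the platform annotation, and 20133 of the tested probe sets named exactly 1 gene, 11528 genes in all. A gene was represented by its probe set with the highest mean over the 9 arrays of the replicated PBMC groups.

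The 12 PBMC arrays were fitted together in limma 3.58.1 under R 4.3.3 (data.table, version 1.17.8) with 6 groups and no other term, and two-sided p-values were adjusted by Benjamini-Hochberg over the 24572 probe sets. Rises and falls are those with an adjusted p below 0.05. A group mean at or below 7.06, the median log2 level of the non-informative probe sets on the PBMC arrays, was taken as background, a choice made after the data were examined. Folds against such a group are lower bounds computed against that level, while log2 changes are as measured, and ranks among them are not certain. A group of 1 array adds nothing to the residual spread and was assumed to vary like the groups of 3. The 293T arrays have no replicates and were compared without a test, by counts of 2-fold differences and by the percentile of a gene list's median among 10000 random lists of its size matched on level in 20 bins. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Before use, the fit was tested on simulated arrays for the 24 h comparison, with the spread pooled over the 3 replicated PBMC groups. It called 32.8% of probe sets shifted by 0.5 on the log2 scale, 65.7% of those shifted by 1 and 92.4% of those shifted by 2. Of the unshifted ones it called 0.037%. The simulated arrays were drawn independently, so these rates do not cover arrays that are repeats or that correlate by number.

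Whether the replicate numbers in the labels pair the samples was checked once. The 9 correlations between deviations from the group mean of arrays that share a number ranged from 0.154 to 0.791, and the 18 between arrays with different numbers from -0.732 to 0.461. What a number stands for is not stated, so the fit had no block, and a fit with the number as a block was an alternative whose value stands beside a count where it differs by over 1.5 times. Arrays numbered 1 and 2 were far closer to each other than to those numbered 3.

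The 27 gene lists were fixed before the data were examined: interferon-stimulated genes, interferon genes, interferon-gamma-induced genes, inflammatory cytokines and NF-kB targets, pattern recognition receptors and adaptors, antiviral restriction factors, metallothioneins and metal response, NRF2 and oxidative stress targets, heat shock proteins, the unfolded protein and integrated stress response, p53 targets, cell cycle genes, scavenger receptors and lysosome, cholesterol synthesis and uptake, glycolysis and hypoxia, T cell activation, MHC class II antigen presentation, ribosomal proteins, the mitochondrial respiratory chain, and markers of monocytes, T cells, B cells, NK and cytotoxic cells, dendritic cells, platelets, erythroid cells and neutrophils. Lists with at least 3 measured genes were tested against all other genes with camera at a preset correlation of 0.01, adjusted over 26 lists, and again with an estimated correlation. Also fixed before the data were examined were the comparisons and the rule for the genes named. For AuNP at 24 h and at 48 h these were the 8 largest rises and 8 largest falls among genes that passed and whose groups did not overlap, and up to 4 genes of each list with the smallest unadjusted p at 24 h. The 5 largest in each direction were taken for 48 h against 24 h, for each single PBMC array and, by the mean over 3 times, for 293T genes that differed from the control one way at all times and had a mean of at least 6. Genes on the Y chromosome, XIST, variable HLA class II genes, GSTM1, GSTT1, receptor segments and unnamed loci were passed over, and list members named beyond the rule were picked after their values were seen.

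The alternatives were a filter on low values, quantile normalization, centring each array on its median, array weights, a trended and robust variance, a SAM-type statistic, only the 2 groups compared, a 2-fold bound, the mean of all probe sets of a gene, the PBMC-only matrix, the replicate block and leaving out each replicate in turn. Chosen after the data were examined were the adjustment over all probe sets, averaging the arrays numbered 1 and 2, and leaving out those numbered 3. Also chosen then were array weights by another method and the ACTB 3' minus 5' difference as a covariate.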

Results

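In PBMCs given AuNP for 24 h, IL1B, which encodes the pro-inflammatory cytokine interleukin-1 beta, rose 34.7-fold (log2 change 5.12, SE 0.20, adjusted p = 3.88e-06; 3 arrays against 3 controls). The metallothionein MT1M, a metal-binding protein, rose at least 22.2-fold (5.02, SE 0.38). The interferon-stimulated antiviral genes RSAD2, IFI44L and IFIT1 rose 14.9-fold (3.90, SE 0.16), 14.2-fold (3.83, SE 0.16) and 14.1-fold (3.82, SE 0.18). Among the largest falls were GPNMB, a lysosomal glycoprotein, 28.7-fold (-4.84, SE 0.51), the mannose receptor MRC1 at least 20.2-fold (-4.60, SE 0.18) and FGL2, a secreted fibrinogen-like protein, at least 22-fold (-4.59, SE 0.20). SELENOP, a selenium carrier, fell at least 14.8-fold (-4.15, SE 0.12, adjusted p = 1.06e-06).

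The other largest rises at 24 h were G0S2 (4.24, SE 0.24), which restrains lipolysis, the integrin subunit ITGB8 (3.91, SE 0.47) and TNFAIP6 (3.64, SE 0.37), a secreted protein induced by tumour necrosis factor. The other largest falls were the lysosomal fucosidase FUCA1 (-4.05, SE 0.45), the chemokine CXCL9 (-4.04, SE 0.45), the beta-glucan receptor CLEC7A (-3.97, SE 0.33) and the monocyte lectin FCN1 (-3.94, SE 0.30). Of 24572 probe sets, 1617 rose and 4373 fell, in 893 and 1972 of 11528 genes, and 426 and 728 of them changed at least 2-fold. With the array number as a block 9156 probe sets changed in place of 5990, and with arrays numbered 1 and 2 averaged 469. If those arrays are repeats of 1 sample, the p-values given here are too small. The count depended on single arrays numbered 1 and 2: it was 3833 without control array 1, 2922 without control array 2, 3083 without AuNP 24 h array 1 and 3184 without AuNP 24 h array 2. The groups did not overlap in 10386 probe sets (42.3%). Chance gives 10% for 6 independent arrays and more if arrays numbered 1 and 2 are repeats. The median of the tested values on the AuNP 24 h arrays lay 0.134 below that of the controls. Scaling moved the split between rises and falls: 27.0% of changes were upward as deposited, 54.1% after median centring and 49.2% after quantile normalization.

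All 29 measured interferon-stimulated genes rose at 24 h, with a median log2 change of 2.35 (adjusted p = 1.89e-32, adjusted p = 0.142 with an estimated correlation), and 29 rose when adjusted over the list alone. Among them were IFI44 (3.44, SE 0.12), an interferon-induced protein that restrains viral replication, and CMPK2 (3.11, SE 0.14), a mitochondrial nucleotide kinase. None of the 4 interferon genes measured passed. IFNB1 stood at 0.04 (SE 0.07), IFNA1 at -0.05 (SE 0.09) and IFNA2 at 0.04 (SE 0.09), and the list median was 0.04 (adjusted p = 0.384). These named genes lay below the background of 7.06 on each control and AuNP array, at 6.54 to 6.86. Values near 0 therefore cannot show that their transcripts were unchanged. IFNG (0.78, SE 0.34, adjusted p = 0.125) passed only with the array number as a block or without AuNP 24 h array 3 (1.16). Interferon-gamma-induced genes split, with 3 of 17 higher and 4 lower (3 and 5 over the list alone; median 0.49, adjusted p = 0.384). The signalling inhibitor SOCS1 rose (1.87, SE 0.34), while the T-cell-attracting chemokines CXCL9 and CXCL11 (-1.36, SE 0.24) and CIITA (-1.25, SE 0.16), the master regulator of MHC class II genes, fell. Of 12 antiviral restriction factors, 4 rose and 1 fell (5 and 2 over the list alone; median 0.48, adjusted p = 0.011, adjusted p = 0.504 with an estimated correlation). Rises were seen in the double-stranded RNA kinase EIF2AK2 (1.80, SE 0.12), TRIM25 (1.24, SE 0.07) and TRIM22 (0.88, SE 0.13). Of 26 pattern recognition receptors and adaptors, 7 rose and 4 fell, also over the list alone (median 0.04, 0.14 relative to all genes, adjusted p = 0.216). The RNA-sensing cofactor DHX58 (2.02, SE 0.12) and NOD1 (0.91, SE 0.08) rose and the surface receptors TLR4 (-1.86, SE 0.14) and TLR5 (-1.08, SE 0.10) fell.

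Inflammatory cytokines and NF-kB targets rose at 24 h in 17 of 25 genes and fell in none (19 over the list alone; median 1.67, adjusted p = 7.01e-16). This was the list that still passed when the correlation was estimated (0.00222). IL1RN, the receptor antagonist of interleukin-1, rose 2.86 (SE 0.13), PTGS2, the inducible cyclooxygenase, 2.41 (SE 0.14), and NFKBIA, the inhibitor that NF-kB itself induces, 1.29 (SE 0.11).

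Of 9 metallothionein and metal response genes, 7 rose at 24 h (7 over the list alone; median 3.03, adjusted p = 1.86e-08, adjusted p = 0.328 with an estimated correlation). Among them were MT1H (3.23, SE 0.25), MT1G (3.22, SE 0.27) and MT2A (3.03, SE 0.25). Shared probes among metallothionein genes were not tested for, so the genes counted may not be separate rises. NRF2 and oxidative stress targets changed in 1 of 12 genes (1 over the list alone; median 0.00, 0.11 relative to all genes, adjusted p = 0.607). The 1 was GCLC, a subunit of the enzyme that starts glutathione synthesis (-0.80, SE 0.17), which did not pass without control array 2 (-0.77) or AuNP 24 h array 1 (-0.72). HMOX1 stood at -1.48 (SE 0.73, adjusted p = 0.173) and passed with the array number as a block and without AuNP 24 h array 3 (-2.36). The median of the NRF2 list ranged from -0.355 to 0.927 over the AuNP 24 h arrays, highest on array 3. Of 10 heat shock proteins, 2 fell, also over the list alone (median -0.11, -0.01 relative to all genes, 0.02 after median centring, adjusted p = 0.552). HSPA6 (-0.77, SE 0.21) was 1 of them, and it did not pass after quantile normalization (-0.66) or without AuNP 24 h array 1 (-0.85), 2 (-0.74) or 3 (-0.70). The other, HSPB1 (-0.99, SE 0.27), did not pass without control array 1 (-0.76) or 2 (-0.98) or AuNP 24 h array 1 or 2 (-0.81). In the unfolded protein and integrated stress response 2 of 15 genes rose and 2 fell (3 and 2 over the list alone; median 0.14, 0.24 relative to all genes, adjusted p = 0.384). The stress transcription factor DDIT3 was up (0.81, SE 0.14) and HERPUD1, which serves protein degradation at the endoplasmic reticulum, was down (-0.51, SE 0.07). Of 12 p53 targets the death receptor FAS rose (1.22, SE 0.18) and 3 fell, as over the list alone. These included ZMAT3 (-1.02, SE 0.16) and TP53I3 (-0.96, SE 0.11). The list median was -0.19 (-0.09 relative to all genes, adjusted p = 0.943). Cell cycle genes changed in 1 of 20 and in 0 over the list alone (median -0.19, -0.09 relative to all genes, adjusted p = 0.451), and the list passed without control array 3 (-0.33).

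Scavenger receptor and lysosome genes fell at 24 h in 10 of 18 (14 over the list alone; median -1.53, adjusted p = 8.79e-06, adjusted p = 0.374 with an estimated correlation). Among them were the lipid scavenger CD36 (-2.89, SE 0.15), the inhibitory Fc receptor FCGR2B (-2.46, SE 0.10) and the lysosomal lipase LIPA (-2.70, SE 0.21). In MHC class II antigen presentation 8 of 12 genes fell and 2 rose (9 and 2 over the list alone; median -1.15, adjusted p = 0.00161, adjusted p = 0.374 with an estimated correlation). HLA-DMB (-2.40, SE 0.09) and HLA-DMA (-2.23, SE 0.13), which load peptides onto class II molecules, and HLA-DPB1 (-1.88, SE 0.15) fell. Monocyte markers moved with these groups: 6 of 14 fell, also over the list alone (median -1.63, adjusted p = 0.00384, adjusted p = 0.504 with an estimated correlation). MNDA stood at -2.21 (SE 0.18) and TNFSF13 at -2.73 (SE 0.21) beside FCN1 and CLEC7A. The list medians on AuNP 24 h arrays 1, 2 and 3 were -1.93, -2.12 and -0.29. The ACTB 3' minus 5' difference, a sign of RNA quality, also moved, at 2.48 (SD 0.121) against 1.70 (SD 0.505) in controls (exact p = 0.1, the smallest for 3 against 3). That of GAPDH was 1.62 (SD 0.199) against 1.48 (SD 0.132, exact p = 0.3).

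Glycolysis and hypoxia genes rose at 24 h in 4 of 14 and fell in 1, also over the list alone (median 0.12, 0.22 relative to all genes, adjusted p = 0.00383, adjusted p = 0.328 with an estimated correlation). VEGFA, a growth factor for blood vessels (2.25, SE 0.17), the vasodilator peptide ADM (2.23, SE 0.17) and PFKFB3, which speeds glycolysis (2.01, SE 0.28), rose. T cell activation genes rose in 4 of 11, also over the list alone (median 0.71, adjusted p = 0.000482, adjusted p = 0.423 with an estimated correlation). These included the interleukin-2 receptor chain IL2RA (1.31, SE 0.19) and the checkpoint receptor CTLA4 (0.92, SE 0.09). In cholesterol synthesis and uptake 1 of 8 genes changed, also over the list alone (median 0.18, 0.29 relative to all genes, adjusted p = 0.126): LSS, which closes the sterol rings, rose (1.07, SE 0.16), and SQLE stood at 0.71 (SE 0.24, adjusted p = 0.0623). SQLE passed with the array number as a block, after quantile normalization (0.83) and over gene means (0.31). Ribosomal proteins fell in 10 of 13 genes (12 over the list alone; median -0.48, -0.38 relative to all genes, -0.29 after quantile normalization, adjusted p = 0.000282, adjusted p = 0.282 with an estimated correlation), by small amounts, such as RPL3 (-0.72, SE 0.09) and RPS16 (-0.60, SE 0.10). In the mitochondrial respiratory chain 3 of 19 fell, and 0 over the list alone (median -0.44, -0.34 relative to all genes, adjusted p = 0.00855, adjusted p = 0.504 with an estimated correlation). None of the 3, UQCRB (-0.54), UQCRQ (-0.60) and ATP5PO (-0.64), passed after quantile normalization or without control array 1 or 2 or AuNP 24 h array 1 or 2.

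Markers of T cells fell in 3 of 14 genes at 24 h, also over the list alone (median -0.20, -0.10 relative to all genes, adjusted p = 0.607). CD3G (-0.92, SE 0.18), a chain of the T cell receptor complex, was 1 of them. LEF1, another, did not pass after quantile normalization (-0.21) or without any single control or AuNP 24 h array. IL7R did not pass after quantile normalization (-0.23). Among B cell markers 5 of 11 fell, also over the list alone (median -0.15, -0.05 relative to all genes, adjusted p = 0.219). These included FCRL1 (-0.99, SE 0.10) and CD79B (-0.94, SE 0.13), a chain of the B cell receptor. TCL1A did not pass without control array 1 or 2 or AuNP 24 h array 1 or 2. VPREB3 did not pass after quantile normalization (-0.23) or without control array 1 or 2 or AuNP 24 h array 2. NK and cytotoxic cell markers fell in 4 of 12, also over the list alone (median -0.40, -0.30 relative to all genes, adjusted p = 0.384). The lectin receptors KLRB1 (-2.24, SE 0.24) and KLRF1 (-0.83, SE 0.14) were among them. KLRD1 and NKG7, also among them, did not pass after quantile normalization (-0.72 and -0.87). Nor did they pass without control array 1 or 2 or AuNP 24 h array 1 or 2. Of 9 dendritic cell markers 3 fell and 1 rose, also over the list alone (median -0.65, adjusted p = 0.407). CLEC10A (-3.50, SE 0.18) and FCER1A (-1.56, SE 0.15) fell, and LAMP3 (1.96, SE 0.14), a marker of mature dendritic cells, rose. Neutrophil markers fell in 7 of 8, also over the list alone (median -1.26, adjusted p = 0.00034, adjusted p = 0.261 with an estimated correlation). These included the chemokine receptor CXCR2 (-1.26, SE 0.12) and CAMP (-1.10, SE 0.17), an antimicrobial peptide. Of 3 platelet markers 2 fell (3 over the list alone; median -1.19, adjusted p = 0.123), and both depended on single arrays. PF4 (-1.29, SE 0.31) did not pass without AuNP 24 h array 1 (-1.30) or 2 (-1.32). PPBP (-1.19, SE 0.31) did not pass without control array 1 (-1.31), 2 (-1.32) or 3 (-0.94) or AuNP 24 h array 1 (-1.31), 2 (-1.31) or 3 (-0.96). HBB, the erythroid marker measured, stood at -0.16 (SE 0.28, adjusted p = 0.714).

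**Figure D1:**
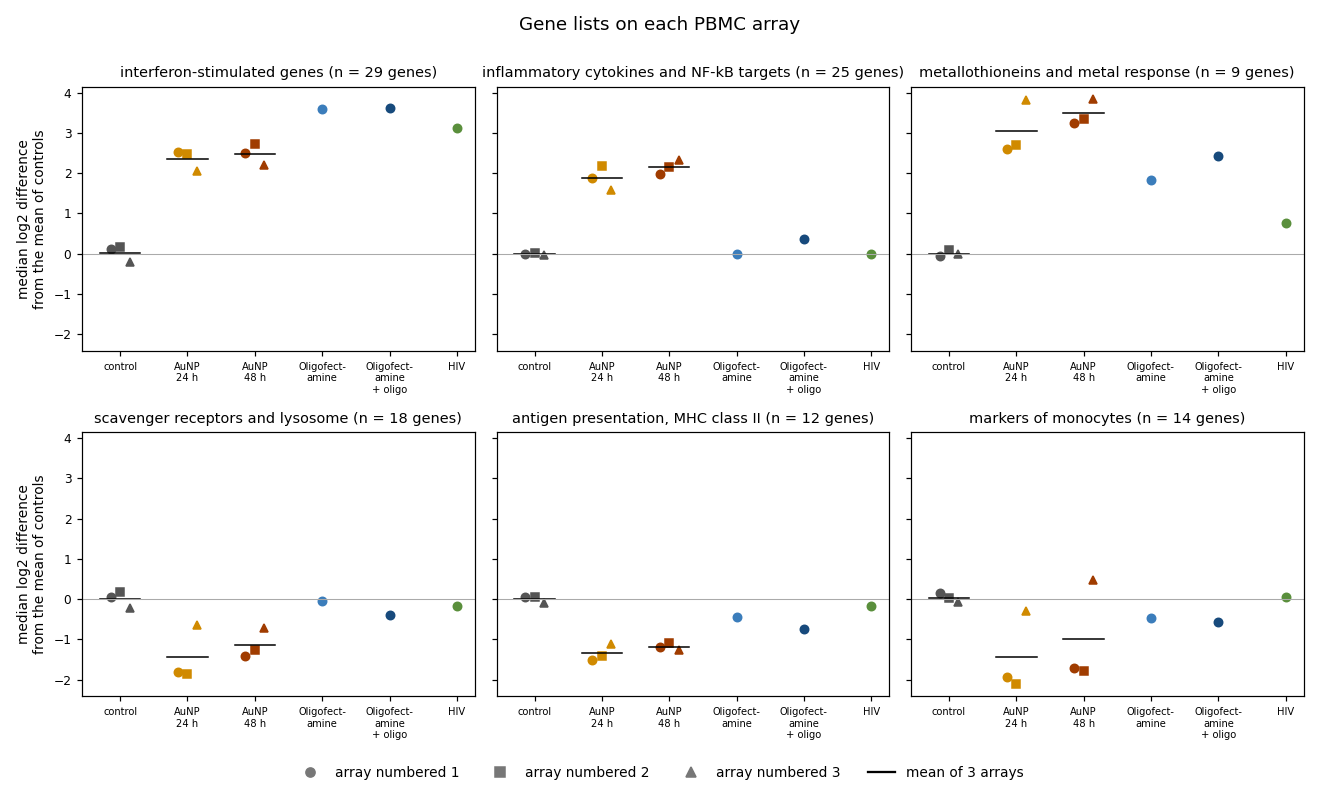
Median log2 difference from the mean of the controls for 6 gene lists on each PBMC array. Monocyte markers stood at -1.93 and -2.12 on AuNP 24 h arrays 1 and 2 and at -0.29 on array 3. The scaling of arrays moved the median of the list from -1.63 as deposited to -1.54 after quantile normalization and -1.49 after median centring.

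After 48 h with AuNP, IL1B stood 52.7-fold above control (5.72, SE 0.20, adjusted p = 2.32e-06; 3 arrays against 3), MT1M at least 31.7-fold (5.54, SE 0.38) and TNFAIP6 38.9-fold (5.28, SE 0.37). ACOD1, the macrophage enzyme that makes itaconate, rose at least 27.1-fold (4.88, SE 0.22), G0S2 26.6-fold (4.73, SE 0.24) and ITGB8 at least 14.8-fold (4.69, SE 0.47). IL1RN rose 24.3-fold (4.60, SE 0.13) and PTGS2 by 4.32 (SE 0.14). MRC1 fell at least 20.2-fold (-4.70, SE 0.18), GPNMB 23.7-fold (-4.57, SE 0.51), FGL2 at least 22-fold (-4.51, SE 0.20) and SELENOP at least 14.8-fold (-4.22, SE 0.12). CXCL9 (-4.11, SE 0.45), the protease inhibitor A2M (-3.96, SE 0.23), FCN1 (-3.85, SE 0.30) and FUCA1 (-3.82, SE 0.45) completed the largest falls.

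At 48 h 2304 probe sets rose and 4807 fell, in 1202 and 2374 genes, and 772 and 697 of them changed at least 2-fold. The total of 7111 became 846 with arrays numbered 1 and 2 averaged, 4079 without control array 2, 4212 without AuNP 48 h array 1 and 4450 without AuNP 48 h array 2. The groups did not overlap in 10861 probe sets (44.2%), where chance gives 10% for independent arrays and more for repeats. As deposited 32.4% of the changes were rises, against 45.4% after median centring and 43.3% after quantile normalization. Changes at both times ran together: 1332 probe sets rose at both (151.6 by independence), 3410 fell at both (855.5) and 0 changed in opposite ways, where independence takes no account of the shared controls. The log2 changes correlated at r = 0.910 (Spearman 0.876, covariance 0.280). This fell to 0.850 without AuNP 24 h array 3 and 0.880 without AuNP 48 h array 3. The same 3 controls served both times, and simulated arrays that held noise alone gave a covariance of 0.0233, which at the observed spreads comes to r = 0.0759. That simulation drew arrays independently, while AuNP 24 h and 48 h arrays of the same number correlated at 0.612 to 0.791 about their group means. The simulated values are therefore a low floor.

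Interferon-stimulated genes stayed up at 48 h in 29 of 29, also over the list alone (median 2.56, adjusted p = 6.42e-28, adjusted p = 0.196 with an estimated correlation). RSAD2 stood at 4.06 (SE 0.16), IFI44L at 3.95 (SE 0.16), IFI44 at 3.27 (SE 0.12) and CMPK2 at 3.18 (SE 0.14). IFNG, which encodes interferon-gamma, rose (1.49, SE 0.34), the 1 of 4 interferon genes to pass (1 over the list alone; median 0.03, 0.11 relative to all genes, adjusted p = 0.293), while IFNB1 stood at 0.07 (SE 0.07). IFNB1 was again below background on control and AuNP arrays. Interferon-gamma-induced genes again split, 4 of 17 up and 3 down (5 and 4 over the list alone; median 0.63, adjusted p = 0.115), and the list passed with the array number as a block and without control array 1 (0.88). SOCS1 stood at 2.28 (SE 0.34), CXCL11 at -1.38 (SE 0.24) and CIITA at -1.37 (SE 0.16). Antiviral restriction factors rose in 5 of 12 and fell in 1 (5 and 2 over the list alone; median 0.50, adjusted p = 0.0122, adjusted p = 0.486 with an estimated correlation). EIF2AK2 stood at 1.81 (SE 0.12) and TRIM25 at 1.44 (SE 0.07). Pattern recognition receptors and adaptors rose in 10 of 26 and fell in 4, also over the list alone. DHX58 stood at 2.24 (SE 0.12) and TLR4 at -1.76 (SE 0.14). Their median was 0.14 (0.21 relative to all genes, adjusted p = 0.0456, adjusted p = 0.262 with an estimated correlation), and the list did not pass after quantile normalization, over gene means, or without control array 2 (0.17), control array 3 (0.08) or AuNP 48 h array 3 (0.20).

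Inflammatory cytokines and NF-kB targets rose at 48 h in 22 of 25 genes (23 over the list alone; median 2.62, adjusted p = 5.43e-19, adjusted p = 0.00131 with an estimated correlation). NFKBIA stood at 1.65 (SE 0.11). The cytokines IL6 (3.45) and TNF (1.38), picked after their values were seen, were among them. Metallothionein and metal response genes rose in 8 of 9, also over the list alone (median 3.44, adjusted p = 3.51e-08, adjusted p = 0.273 with an estimated correlation). MT1H stood at 3.65 (SE 0.25) and MT2A at 3.40 (SE 0.25), and as at 24 h shared probes were not tested for. The unfolded protein and integrated stress response had 7 of 15 genes up and 5 down (8 and 5 over the list alone; median 0.59, adjusted p = 0.0914). DDIT3 rose 2.02-fold (SE 0.14 on the log2 scale). CHAC1 (log2 change 1.74) and SESN2 (log2 change 1.95), targets of the transcription factor ATF4 picked after their values were seen, also rose. The endoplasmic reticulum chaperone genes DNAJB9 (-1.12, SE 0.17) and, also picked so, HSPA5 (-0.94) fell. Among p53 targets 4 of 12 rose and 3 fell (5 and 4 over the list alone; median 0.06, 0.13 relative to all genes, adjusted p = 0.595). FAS stood at 1.25 (SE 0.18) and ZMAT3 at -1.34 (SE 0.16). NRF2 and oxidative stress targets changed in 1 of 12, also over the list alone (median 0.10, 0.18 relative to all genes, adjusted p = 0.515), GCLC at -0.94 (SE 0.17). SLC7A11, the cystine transporter (2.32, SE 0.86, adjusted p = 0.0764), passed only with the array number as a block. Heat shock proteins fell in 3 of 10 (6 over the list alone; median -0.43, adjusted p = 0.115; passing without control array 3, -0.52), such as the cochaperone BAG3 (-0.40, SE 0.10). HSPB1 (-0.86), another, did not pass after quantile normalization (-0.82) or without control array 1 (-0.62) or 2 (-0.84) or AuNP 48 h array 1 (-0.91), 2 (-0.74) or 3 (-0.92). Cell cycle genes fell in 2 of 20 (1 over the list alone; median -0.17, -0.09 relative to all genes, adjusted p = 0.19; passing without control array 3, -0.28), such as the replication clamp PCNA (-0.85, SE 0.17).

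Scavenger receptor and lysosome genes were down at 48 h in 9 of 18 (11 over the list alone; median -1.33, adjusted p = 0.000403, adjusted p = 0.448 with an estimated correlation). LIPA stood at -2.98 (SE 0.21), CD36 at -2.92 (SE 0.15) and FCGR2B at -2.37 (SE 0.10). MHC class II genes fell in 8 of 12 and rose in 2, also over the list alone (median -1.15, adjusted p = 0.0168, adjusted p = 0.486 with an estimated correlation). HLA-DMB stood at -2.35 (SE 0.09) and HLA-DPA1 at -1.47 (SE 0.13). The pair that rose, picked after their values were seen, were the costimulatory ligand CD80 (2.20) and the dendritic cell maturation marker CD83 (1.09). Beside them, 6 of 14 monocyte markers fell and 1 rose, also over the list alone (median -1.08, adjusted p = 0.0873), and the list passed after quantile normalization (-1.05) and without AuNP 48 h array 3 (-1.73). FCN1, CLEC7A (-3.47, SE 0.33) and TNFSF13 (-2.69, SE 0.21) were among those that fell. The list medians on AuNP 48 h arrays 1, 2 and 3 were -1.70, -1.78 and 0.48. The ACTB 3' minus 5' difference was 2.33 (SD 0.225) against 1.70 in controls (exact p = 0.2, or exact p = 0.0238 for both times together). The p for both times takes all arrays as independent, though AuNP arrays of the same number correlated and those numbered 1 and 2 may be repeats. The highest control, 2.284, lay within the AuNP range of 2.125 to 2.603. The GAPDH difference was 1.76 (SD 0.333) against 1.48 (exact p = 0.4).

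The glycolysis and hypoxia list had 5 of 14 genes up and 1 down at 48 h, also over the list alone (median 0.16, 0.24 relative to all genes, adjusted p = 0.00258, adjusted p = 0.267 with an estimated correlation). ADM stood at 3.46 (SE 0.17) and VEGFA at 2.91 (SE 0.17). T cell activation genes rose in 6 of 11, also over the list alone (median 0.72, adjusted p = 0.000314, adjusted p = 0.448 with an estimated correlation). IL2RA stood at 2.06 (SE 0.19). In cholesterol synthesis and uptake LSS rose (1.57, SE 0.16) and 2 of 8 genes fell, also over the list alone (median 0.10, 0.17 relative to all genes, adjusted p = 0.636). Ribosomal proteins fell in 10 of 13 (13 over the list alone; median -0.37, -0.30 relative to all genes, -0.23 after quantile normalization, adjusted p = 0.000487, adjusted p = 0.262 with an estimated correlation). RPL3 stood at -0.71 (SE 0.09). Respiratory chain genes fell in 10 of 19 (13 over the list alone; median -0.61, adjusted p = 0.00258, adjusted p = 0.486 with an estimated correlation), with the complex III subunit UQCRB at -1.03 (SE 0.17) and ATP5PO of the ATP synthase at -0.90 (SE 0.17).

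Among other cell type markers at 48 h, T cell markers fell in 3 of 14 (median -0.23, -0.16 relative to all genes, adjusted p = 0.623). CD3G stood at -0.92 (SE 0.18). IL7R, another, did not pass after quantile normalization (-0.27). B cell markers fell in 4 of 11 (median -0.21, -0.14 relative to all genes, adjusted p = 0.705). FCRL1 stood at -0.66 (SE 0.10). CD79B did not pass without control array 1 (-0.52) or 2 (-0.49), and VPREB3 did not after quantile normalization (-0.24). NK and cytotoxic cell markers fell in 3 of 12 (median -0.42, -0.35 relative to all genes, adjusted p = 0.522). KLRB1 stood at -1.93 (SE 0.24). KLRD1, another, did not pass without control array 1 (-0.73) or 2 (-0.84) or any single AuNP 48 h array. Adjusted over each list alone, these counts were 3, 4 and 3. Dendritic cell markers fell in 4 of 9 and rose in 2 (6 and 3 over the list alone; median -0.78, adjusted p = 0.394). CLEC10A stood at -3.62 (SE 0.18) and LAMP3 at 2.09 (SE 0.14). Neutrophil markers fell in 7 of 8, also over the list alone (median -1.17, adjusted p = 0.00203, adjusted p = 0.262 with an estimated correlation). CXCR2 stood at -1.18 (SE 0.12). Platelet markers fell in 2 of 3, also over the list alone (median -2.38, adjusted p = 0.0397, adjusted p = 0.286 with an estimated correlation): the chemokines PPBP (-3.08, SE 0.31) and PF4 (-2.38, SE 0.31). The platelet list did not pass with the array number as a block or without AuNP 48 h array 3 (-2.55). HBB stood at -0.17 (SE 0.28, adjusted p = 0.682).

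Between 24 h and 48 h with AuNP, few single genes passed (3 arrays against 3). PTGS2 rose 3.77-fold (1.91, SE 0.14, adjusted p = 0.00343), IL36G, an epithelial interleukin-1 family cytokine, 3.58-fold (1.84, SE 0.19), and IL1RN 3.34-fold (1.74, SE 0.13). The extracellular matrix gene PAPLN (1.88, SE 0.24) and the autophagy gene MAP1LC3A (1.74, SE 0.21) also rose. CRELD2, a chaperone-like protein of the endoplasmic reticulum, was the single gene to fall (-0.87, SE 0.11). No probe set fell with the filter on low values, a trended and robust variance or the PBMC-only summaries. The same held with the adjustment over all probe sets, or without array 1 or 2 of either time. The platelet chemokines PPBP (-1.89, SE 0.31, adjusted p = 0.118) and PF4 (-1.09, SE 0.31, adjusted p = 0.316) did not pass. Nor did the chaperone HSP90B1 (-1.45, SE 0.37, adjusted p = 0.27) and RGS18 (-1.14, SE 0.24, adjusted p = 0.178). These had the largest falls among the genes whose 24 h and 48 h arrays did not overlap.

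Inflammatory cytokines and NF-kB targets gained further from 24 h to 48 h as a list (median 0.60, adjusted p = 9.35e-14, adjusted p = 0.00316 with an estimated correlation), with 2 of 25 genes past and 14 over the list alone. Metallothionein and metal response genes (median 0.42, adjusted p = 0.0336, adjusted p = 0.805 with an estimated correlation), B cell markers (0.32, adjusted p = 0.0336, adjusted p = 0.718 with an estimated correlation) and, downward, platelet markers (-1.09, adjusted p = 0.039, adjusted p = 0.412 with an estimated correlation) also passed with none of their genes past, or with 0, 2 and 2 over the list alone. Interferon-stimulated genes did not differ (median 0.09, adjusted p = 0.351). In all, 22 probe sets rose and 1 fell, 14 at least 2-fold, beside 2334 with an unadjusted p below 0.05, and 59 changed with the array number as a block. In limma with only these 2 groups 0 passed (2282 at an unadjusted p below 0.05), and with arrays numbered 1 and 2 averaged 0 (516), against 173 by the SAM-type statistic. The total of 23 became 6 without AuNP 24 h array 1 or 2 or AuNP 48 h array 1 or 2, 399 without AuNP 24 h array 3 and 319 without AuNP 48 h array 3. The groups did not overlap in 14.4% of probe sets. As arrays of the same number were correlated, the 10% that chance gives for independent arrays is no sure floor for it.

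**Figure D2:**
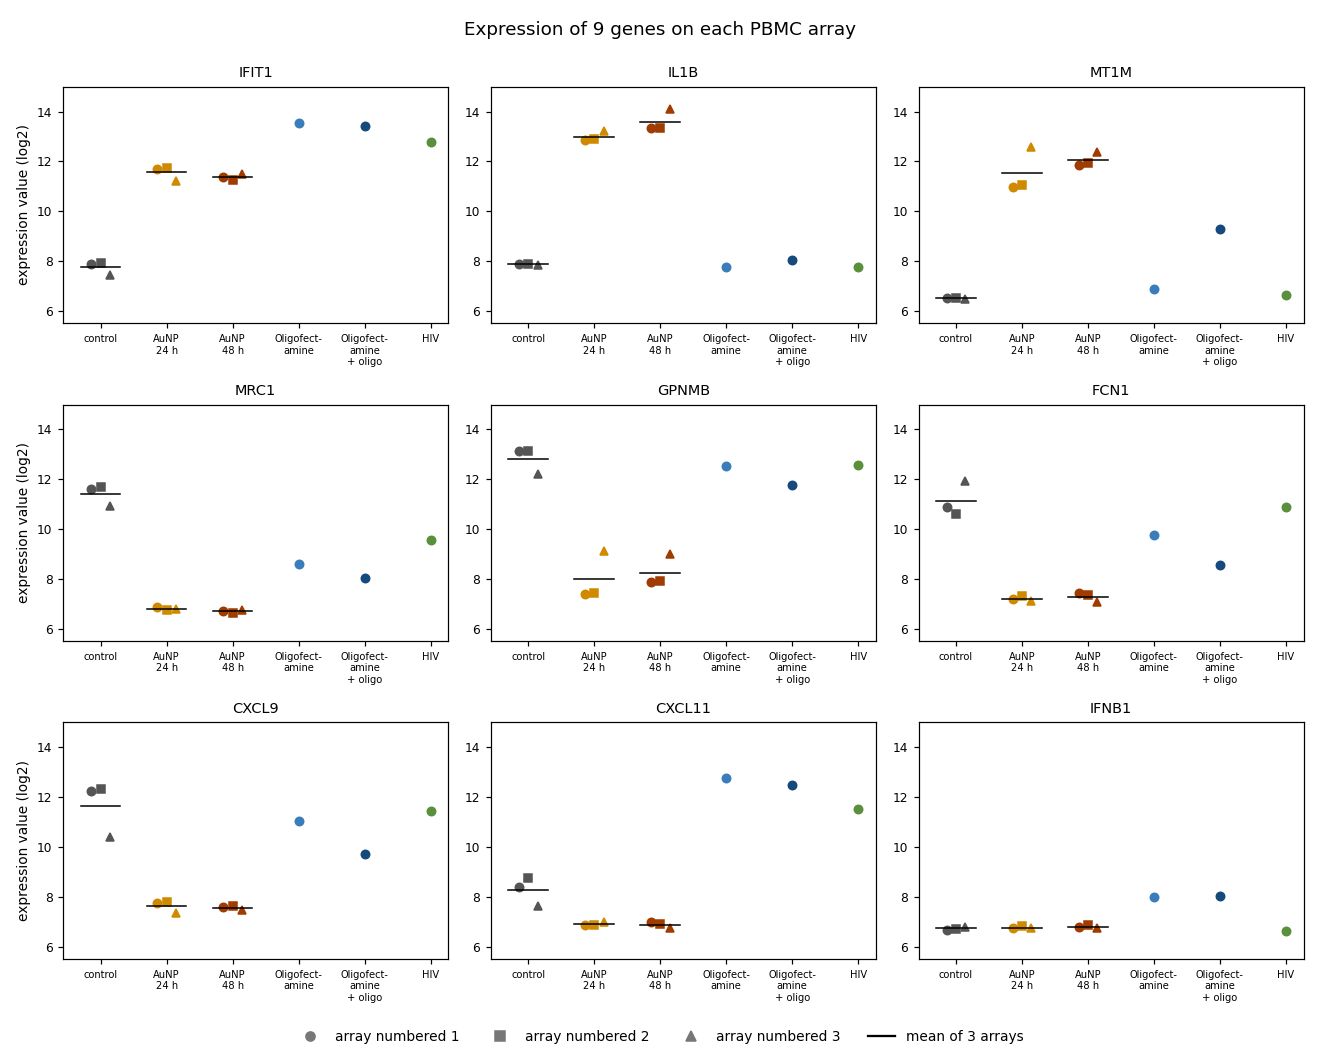
Expression of 9 genes on each PBMC array, on the log2 scale. IL1B rose by 5.12 at 24 h with AuNP and CXCL11 fell by 1.36, while CXCL11 stood 4.52 above the controls on the Oligofectamine array.

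On the single array of Oligofectamine alone, set against 3 controls, IFIT1 stood 54.9-fold above control (5.78, SE 0.26, adjusted p = 3.41e-05) and RSAD2 46.2-fold (5.53, SE 0.23). SEs and p-values for single arrays borrow the spread of the groups of 3 and cannot part the treatment from the culture, donor or time of that array. The chemokines CCL8 (5.00, SE 0.72) and CXCL11 (4.52, SE 0.34) and the ubiquitin-like ISG15 (4.50, SE 0.35) also rose. SELENOP fell 10.6-fold (-3.41, SE 0.16), the coagulation factor subunit F13A1 8.20-fold (-3.04, SE 0.14) and MRC1 6.98-fold (-2.80, SE 0.25). GGTA1 (-2.49, SE 0.12) and the metalloreductase STEAP4 (-2.33, SE 0.24) fell too. With the EGFP oligonucleotide added, IFIT1 (5.66, SE 0.26), RSAD2 (5.44, SE 0.23), CCL8 (5.20, SE 0.72), ISG15 (4.47, SE 0.35) and NUPR1, a stress-induced chromatin protein (4.56, SE 0.31), rose most. SELENOP (-4.08, SE 0.16), F13A1 (-3.65, SE 0.14), MRC1 (-3.35, SE 0.25), A2M (-3.02, SE 0.33) and GGTA1 (-2.59, SE 0.12) fell most. On the HIV array, IFIT1 (5.05, SE 0.26), RSAD2 (4.87, SE 0.23), IFI44L (4.17, SE 0.22), ISG15 (3.95, SE 0.35) and OAS1 (3.76, SE 0.32) rose. F13A1 (-1.98, SE 0.14), GGTA1 (-1.84, SE 0.12), MRC1 (-1.83, SE 0.25), SELENOP (-1.55, SE 0.16) and MOB3B (-0.87, SE 0.12) fell.

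Interferon-stimulated genes rose in 28 of 29 on both Oligofectamine arrays and in 25 of 29 on the HIV array (29 over the list alone on each), with medians of 3.60, 3.62 and 3.12 and adjusted p = 0.033, 0.0195 and 0.0122 with an estimated correlation. Interferon genes themselves were higher in 3 of 4 on both Oligofectamine arrays (adjusted p = 0.0299 and 0.0195 with an estimated correlation): IFNB1 by 1.28 and 1.31, IFNA1 by 1.65 and 1.35 and IFNA2 by 1.27 and 1.55. On the HIV array none of the 4 passed. IFNB1 stood at -0.09 there, also below background (list median -0.10). Pattern recognition receptors and adaptors rose in 8, 6 and 1 of 26 genes (8, 7 and 6 over the list alone), with adjusted p = 0.0299, 0.0195 and 0.0122 with an estimated correlation. Inflammatory cytokines and NF-kB targets rose in 3, 5 and 1 of 25 (4, 5 and 2 over the list alone), and the list passed with an estimated correlation for Oligofectamine with the oligonucleotide (adjusted p = 0.0195), not for Oligofectamine alone (adjusted p = 0.106) or HIV (adjusted p = 0.979). IL1B, which had the largest measured log2 rise under AuNP, stood at -0.09, 0.17 and -0.10 on the 3 arrays, while IL1RN rose on each, by 4.19, 4.21 and 1.75. Metallothionein and metal response genes rose in 4, 6 and 0 of 9 (5, 7 and 4 over the list alone; medians 1.83, 2.43 and 0.76), with adjusted p = 0.475, 0.268 and 0.723 with an estimated correlation. Monocyte markers rose in 1, 1 and 0 and fell in 0, 1 and 0 of 14, with medians of -0.46, -0.57 and 0.06.

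On Oligofectamine alone 719 probe sets rose and 587 fell, with the oligonucleotide 479 and 445, and on the HIV array 126 and 14. Without control array 2 the totals for Oligofectamine alone and with the oligonucleotide became 725 and 468. Adding the oligonucleotide to Oligofectamine, 1 array against 1, gave 0 calls in limma and 202 probe sets with an unadjusted p below 0.05. A filter on low values, median centring, quantile normalization, a trended and robust variance and gene means also gave 0. The changes on the 3 arrays correlated with those under AuNP at 24 h at r = 0.353, 0.509 and 0.295 (covariances 0.0920, 0.125 and 0.0532), where simulated arrays with shared controls that held noise alone gave a covariance of 0.0233. At the observed spreads this comes to r = 0.0894, 0.0946 and 0.129. The simulation drew arrays independently. Rises shared with AuNP at 24 h numbered 273, 259 and 98 (47.3, 31.5 and 8.29 by independence), shared falls 475, 421 and 14 (104.5, 79.2 and 2.49) and opposite changes 98, 32 and 12, where independence takes no account of the shared controls. The labels give no time for the control, Oligofectamine and HIV arrays. RNA quality may also differ: the GAPDH 3' minus 5' difference was 2.02 on each Oligofectamine array, against 1.39 to 1.63 on controls. It was 1.62 on the HIV array. The ACTB difference, at 1.90 and 2.24 on the Oligofectamine arrays, lay within the control range of 1.37 to 2.28.

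Against the single array of Oligofectamine with the same oligonucleotide, whose time and donor are not stated, the 3 AuNP 24 h arrays stood higher in IL1B (4.95, SE 0.29), G0S2 (4.43, SE 0.34), the activin subunit INHBA (3.46, SE 0.61), ITGB8 (3.41, SE 0.67) and VEGFA (2.84, SE 0.24). They stood lower in CXCL11 (-5.61, SE 0.34), NUPR1 (-5.25, SE 0.31), FUCA1 (-4.57, SE 0.63), FGL2 (-4.11, SE 0.29) and the galectin LGALS2 (-4.09, SE 0.72). Interferon-stimulated genes were lower in 7 of 29 (15 over the list alone; median -1.05, adjusted p = 3.83e-10, adjusted p = 0.343 with an estimated correlation) and interferon genes in 3 of 4 (3 over the list alone; adjusted p = 0.1 with an estimated correlation). Inflammatory cytokines and NF-kB targets were higher in 7 of 25 and lower in 2 (10 and 4 over the list alone; median 1.04, adjusted p = 0.0322 with an estimated correlation). In all 200 probe sets were higher and 634 lower. Of the changes 24.0% were upward as deposited, 42.8% after median centring and 38.1% after quantile normalization. The total of 834 became 384 without AuNP 24 h array 1 and 331 without array 2.

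In 293T cells, where each time had 1 array and nothing was tested, the genes highest by the rule included ATF3 and GDF15. ATF3, a stress-induced transcription factor, stood 0.94, 0.95 and 1.10 above the control at 6 h, 24 h and 48 h, and GDF15, a stress-induced cytokine, 0.98, 0.92 and 1.10. The glycolytic genes PFKFB4 (0.38, 1.25 and 1.34) and HK2 (0.41, 1.16 and 1.23) and FAXDC2 (0.41, 1.17 and 1.20) were higher. The mitochondrially encoded ATP6 (-0.12, -1.29 and -1.51), the haem oxygenase HMOX1 (-0.09, -1.31 and -1.43), the carbonic anhydrase CA2 (-0.43, -0.95 and -1.45), the growth regulator MYC (-0.21, -0.89 and -1.15) and ID2 (-0.52, -0.84 and -0.87) were lower. Differences of at least 2-fold numbered 2, 16 and 33 of 24572 probe sets.

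Lists of stress genes went both ways in 293T cells. The median of p53 targets stood at 0.31, 0.47 and 0.49 at 6 h, 24 h and 48 h, and that of the unfolded protein and integrated stress response at 0.27, 0.34 and 0.56, both at percentile 100 of random lists of matched level. Glycolysis and hypoxia genes stood at 0.07, 0.27 and 0.23 (percentiles 98.3, 100 and 100), heat shock proteins at 0.01, -0.27 and -0.36 (percentiles 54.4, 0.01 and 0) and NRF2 targets at -0.05, -0.19 and -0.18 (13.7, 0.33 and 0.69). The lists that led in PBMCs stayed near 0 in 293T cells at 24 h: interferon-stimulated genes at -0.02, inflammatory cytokines at 0.04 and metallothioneins at -0.06. Changes in PBMCs and 293T cells correlated at r = 0.0333 at 24 h and 0.0514 at 48 h over 11528 genes. The 24 h value became 0.0167 without control array 1, 0.0478 without control array 3 and 0.0214 without AuNP 24 h array 2. Of 647 genes that changed at least 2-fold in PBMCs at 24 h, 1 differed 2-fold in the same direction in 293T cells, C11orf96 (1.82 and 1.06), and FAM13A in the opposite one (-1.66 and 1.04).

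**Figure D3:**
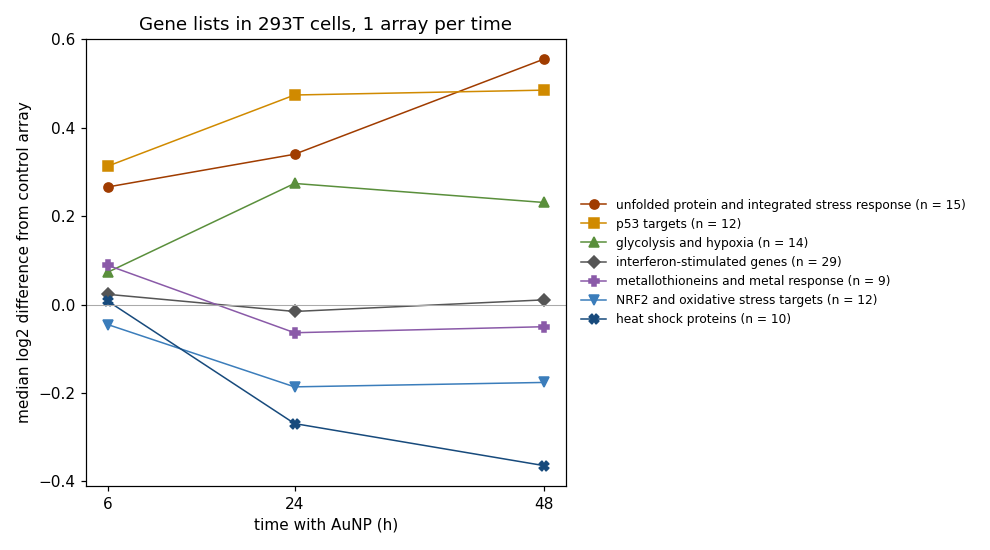
Median log2 difference of 7 gene lists in 293T cells from the control array at 6 h, 24 h and 48 h, with 1 array per time. At 48 h the unfolded protein and integrated stress response stood at 0.56, p53 targets at 0.49 and heat shock proteins at -0.36.

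In the authors' deposited table, which sets the 6 AuNP arrays of PBMCs against all 6 other PBMC arrays, 2055 of 14621 probe sets passed upward and 3949 downward. Inflammatory genes passed upward in 21 of 25 in the authors' deposited table and downward in 1. Metallothionein and metal response genes passed upward in 8 of 9 and scavenger receptor and lysosome genes downward in 14 of 18. Interferon-stimulated genes passed in 3 of 29 in the authors' deposited table (median 0.73). With that contrast in limma they passed in 0 of 29 (median 0.79), against 29 of 29 with the 3 controls alone, and the 6 other arrays include the Oligofectamine and HIV arrays on which these genes were up. For 293T cells that table sets AuNP at 24 h and 48 h against the control together with AuNP at 6 h, so the reference holds a treated array. There 0 of 18506 probe sets passed the SAM test, where the smallest adjusted p was 0.333. With so few arrays on each side, this cannot show that nothing changed in 293T cells.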

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

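Chosen only after the result was seen were the tests of a uniform loss of monocytes, of RNA quality with a covariate, of both AuNP times together over 84 splits, of IFNB1 against shared alpha probes and of the HIV array against the controls.

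The difference between the AuNP effects at 48 h and 24 h stood out because it was tested itself, and it passed for 23 probe sets, 22 higher and 1 lower at 48 h. Of the 23, 14 had already risen at 24 h against control, and these include CRELD2, the lower one. CRELD2 stood at 0.55 at 24 h (adjusted p = 0.0102) and at -0.32 at 48 h (adjusted p = 0.0631). The 1 that had fallen at 24 h (-1.10) has no gene named here and was among the 22 higher. The 23 held 4 probe sets of IL1RN, 3 of MAP1LC3A, PTGS2 and IL36G. With these 6 arrays fitted alone in limma 0 probe sets passed (2282 at an unadjusted p below 0.05, 173 by the SAM-type statistic), and the highest other split also gave 0, so 10 of 10 gave as many. The splits are too few for a share below 0.05.

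MHC class II antigen presentation genes stood lower on all 6 PBMC AuNP arrays (medians -1.50 to -1.10) and slightly higher on all 3 AuNP arrays of 293T cells, at most 0.072; the difference was not tested. These values used the probe sets chosen on PBMC arrays. With genes represented by the probe sets chosen on 293T arrays, as for the 293T lists above, the 24 h median was -0.01, so the opposite directions depend on that choice. Markers of NK and cytotoxic cells stood lower on all 6 PBMC AuNP arrays (-0.68 to -0.28) and slightly higher on the 3 of 293T cells, at most 0.102. The difference was not tested. With probe sets chosen on 293T arrays the medians were 0.07, 0.04 and 0.06 at 6 h, 24 h and 48 h. These lay at percentiles 98.0, 90.1 and 92.6 of random lists, so at 24 h and 48 h such a shift was not rare.

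The number of changes under AuNP was set against other splits of the arrays, fitted alone. At 24 h the real split gave 5111 probe sets and the highest other 0, and at 48 h 6037 and 0, with the real split the 1 of 10 that gave as many, which is too few splits for a share below 0.05. With both times as 1 group of 6, the real split gave 8112 probe sets and was the 1 of 84 that gave as many, so chance can be excluded only if the 9 arrays are independent. Arrays numbered 1 and 2 are close enough to be repeats, and averaged they leave too few splits for a share below 0.05. The highest other, 165, set the 3 arrays numbered 3 against the rest, and the highest of the 27 that part as many pairs of arrays as the real one was 9.

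The fall of monocyte markers at 24 h was weighed against a loss of monocytes, RNA quality and scaling. A uniform loss as the whole cause would shift alike each marker that is read only from monocytes and stays above background. The 95% intervals of 8 of 14 markers leave out their weighted mean of -2.20. Among these, FPR1 (control level 8.85) and S100A12 (8.57) start too near the background of 7.06 to fall so far. But S100A8 (12.01), S100A9 (10.75) and SERPINA1 (10.25) had room to fall. They stood at -0.29, -0.095 and -0.32, while FCN1 stood at -3.94. Other cells may carry these markers too, which was not tested. With the ACTB 3' minus 5' difference as a covariate the list median was -2.44 against -1.63 without, and 4 of the 6 markers that fell still passed, with SEs up to 0.828 in place of 0.532. That fit cannot weigh RNA quality against AuNP. The difference was 2.363 to 2.603 on AuNP 24 h arrays and 1.372 to 2.284 on controls, with no overlap. Among controls it set array 3 (2.284) apart from arrays 1 (1.372) and 2 (1.454), so it also followed the array number. After quantile normalization the median was -1.54, which argues against scaling. A partial loss of monocytes together with a change in their expression may remain, and the markers on AuNP arrays 3 stood apart from those on arrays 1 and 2, the cause of which was not tested.

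IFNB1, IFNA1 and IFNA2 stood higher on both Oligofectamine arrays and did not pass under AuNP, where interferon-stimulated genes were also up. On control and AuNP arrays they lay below the background of 7.06, so an unchanged level under AuNP cannot be read from them. The adjusted p of IFNB1, at most 0.00046 on both arrays with 1 array each, restates its rise, so for IFNB1 too shared probes stay open. For IFNA1 and IFNA2 shared probes cannot be told apart from separate rises, since their changes differed by at most 2.19 SE. The culture or donor of these single arrays stays open too: on the HIV array 1 of the 3 genes lay within the range of the controls, the other pair below it and none above it.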

How the results depend on the processing

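Chosen after the data were examined were the adjustment over all probe sets, averaging or leaving out by array number, and gene-by-gene array weights. So were the ACTB covariate, both AuNP times together and the authors' contrast. No call of a named gene or list reversed in the alternatives run for it. The balance of rises and falls did: 1617 and 4373 at 24 h became 2717 and 2304 after median centring, and 2304 and 4807 at 48 h became 772 and 697 with a 2-fold bound. Total counts at 24 h and 48 h stayed within 1.5 times with a filter on low values, quantile normalization, median centring, a trended and robust variance, the PBMC-only summaries, the SAM-type statistic and the 2 groups alone. Where a count moved, the cause was not tested, except where fewer probe sets, genes or arrays entered or a bound was added by construction. The detection filter was not run. Signal limited what could be tested: 54.95% of probe sets were non-informative and were left out.

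Changed probe sets for AuNP at 24 h, 48 h and 48 h against 24 h (5990, 7111 and 23) became 3161, 3916 and 18 over gene means, 1154, 1469 and 14 with a 2-fold bound, 14914, 15100 and 15574 with array weights, 12813, 13411 and 6386 with gene-by-gene weights, 469, 846 and 0 with arrays numbered 1 and 2 averaged, and 12120, 12729 and 3777 without those numbered 3. The array weights did not converge and reached 15.4 for AuNP 24 h array 2 and 14.2 for AuNP 48 h array 2, against 0.158 to 0.218 for arrays numbered 3. The block gave 9156 at 24 h and 59 for 48 h against 24 h, and the adjustment over all probe sets 3822 and 10. The covariate gave 2839 at 24 h. For 48 h against 24 h the PBMC-only summaries gave 15, the 2 groups alone 0 and the SAM-type statistic 173. Gene means gave 797, 606 and 91 for Oligofectamine, Oligofectamine with the oligonucleotide and HIV, and the 2-fold bound 649 and 495 for the first pair and 503 for AuNP 24 h against the latter. In 293T cells the 2-fold counts of 2, 16 and 33 became 34, 227 and 431 at 1.5-fold and 0, 5 and 12 over gene means, and median centring gave 5 at 6 h. Lists past camera fell from 12 at 24 h and 13 at 48 h to 1 and 1 with an estimated correlation.

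Leaving out each array in turn gave 2922 to 6672 at 24 h, 4079 to 7893 at 48 h, 6 to 399 for 48 h against 24 h, 725 to 1136, 468 to 865 and 95 to 120 for Oligofectamine, Oligofectamine with the oligonucleotide and HIV, 331 to 1083 for AuNP 24 h against the second of these, 4333 to 8209 for both times together, 12 to 13 and 12 to 14 lists, r = 0.850 to 0.918 between times and 0.0167 to 0.0478 between PBMCs and 293T cells. The lone array left in a group was assumed to vary like the others. Over these refits, named genes that passed with all arrays lost their call in 107 of 1116 and those that did not pass gained one in 14 of 234. Lists did so in 4 of 150 and 5 of 162. With arrays numbered 1 and 2 averaged, interferon-stimulated genes passed in 19 of 29 at 24 h and 20 at 48 h, inflammatory genes in 8 and 12 of 25 and metallothionein and metal response genes in 6 and 7 of 9, and of the 16 genes with the largest changes 12 and 15 passed.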

Other observations

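Gene families were chosen after the data were examined, by the stems of their symbols, and tested with camera over 21 families. Poly(ADP-ribose) polymerases, several of which are antiviral, rose in 6 of 13 genes at 24 h and 7 at 48 h, with 1 and 2 lower (medians 0.53 and 0.70, adjusted p = 0.0155 and 0.0283, adjusted p = 0.556 and 0.613 with an estimated correlation). PARP12 rose by 1.44 (SE 0.08) and 1.36, PARP10 by 1.31 (SE 0.13) and 1.25 and PARP9 by 1.30 (SE 0.22) and 1.29. Subunits of the V-type proton pump, which acidifies lysosomes, fell in 6 of 18 at 24 h (median -0.57, -0.46 after quantile normalization, adjusted p = 0.0155, adjusted p = 0.592 with an estimated correlation) and in 5 at 48 h (-0.32, adjusted p = 0.169), with ATP6AP2 at -0.92 (SE 0.16) and -1.37. Translation initiation factors fell in 13 of 42 at 24 h and 16 at 48 h, with 2 and 0 higher (medians -0.27 and -0.27, -0.15 and -0.21 after quantile normalization, adjusted p = 0.0292 and 0.0283, adjusted p = 0.556 and 0.613 with an estimated correlation). EIF4B stood at -1.14 (SE 0.13) and -1.18 and EIF3F at -0.95 (SE 0.09) and -0.79. The symbol stem also took in EIF4EBP1, a binding protein of EIF4E and no initiation factor itself. It was 1 of the 13 at 24 h (-0.73) and stood at -0.08 at 48 h.

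Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, rose in 6 of 14 and fell in 1 at 48 h (median 0.32, adjusted p = 0.0283, adjusted p = 0.71 with an estimated correlation), with GARS1 at 0.82 (SE 0.17), and 1 rose at 24 h (median 0.22, adjusted p = 0.0978). Killer cell lectin-like receptors fell in 5 of 8 at 24 h, including KLRG1 (-1.40, SE 0.24), and the family did not pass (adjusted p = 0.0605). Integrins did not move as a family (adjusted p = 0.753; median -0.09 as deposited, 0.04 after median centring), but ITGAM (-2.74 at 24 h, -2.57 at 48 h) and ITGB2 (-2.17 and -1.92), the chains of the phagocyte complement receptor, fell while ITGB8 rose. Matrix metalloproteinases rose in 2 of 14 at 24 h and 4 at 48 h and fell in 1 and 3, and did not pass (camera adjusted p = 0.37 and 0.133). The collagenase MMP1 rose by 1.58 (SE 0.14) at 24 h and 2.42 at 48 h and MMP19 by 1.53 (SE 0.28) and 2.51. MMP8 fell (-1.04 and -0.79), as did MMP28 at 48 h (-0.82). The cyclic AMP phosphodiesterase PDE4B rose by 1.13 (SE 0.24) and 1.29, while PDE7A fell (-0.54 and -0.64). From 24 h to 48 h, histone genes (median 0.22, 0.16 after quantile normalization, adjusted p = 0.0288, adjusted p = 0.288 with an estimated correlation) and matrix metalloproteinases (median 0.09, 0.03 after quantile normalization, adjusted p = 0.0437, adjusted p = 0.74 with an estimated correlation) passed upward at the preset correlation, with 0 of 17 and 0 of 14 genes past.

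Arrays numbered 1 and 2 lay close together in each group, and what the numbers stand for is not stated. Among pairs within a group, 16 to 1402 probe sets differed 2-fold at 24 h, 19 to 1410 at 48 h and 118 to 660 among controls. Correlations within a group were highest between arrays 1 and 2, at r = 0.983 among controls, 0.990 at 24 h and 0.992 at 48 h. Between an AuNP 24 h and a control array the number was 1392 to 2613, and for 48 h 1798 to 3085.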
